A study of Drosophila melanogaster with 4 samples.

How the data were processed

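DNA bound by L(3)mbt and input DNA were sequenced from 4 samples, 2 per group, each group holding 1 sample of w1118 and 1 of Canton S. Per the labels' protocols, libraries were prepared with the Illumina kit for ChIP-seq and the antibody was raised in guinea pig against a part of L(3)mbt. Bowtie is named in the submitters' processing notes, without a version. The peak caller is named pypeak in the deposited lists' own names, and its settings, the genome build and whether reads of both strains were pooled are not given in the sources used here. The chromosome names, with Het, U and Uextra scaffolds, are those of Drosophila release 5. The gene table at hand was for release 6 and no genome sequence was used, so coordinates were not joined to genes. Tests of positions relative to genes, of gene lists, of motifs and of divergent promoters, planned for the case of a matching release, were not run.

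The deposited lists hold 3314 and 4572 filtered ChIP peaks, 18529 unfiltered ChIP peaks and 46603 input peaks. Each of the 4 deposited lists gives one signal value per peak, made by the authors' caller. In both filtered lists the regions are 400 bp wide, and the deposited signal multiplied by the width was a whole number for 100% of peaks, within 0.01. It was therefore read as a mean per base over the region, which no source used here states, and is called the score here. Whether input was subtracted is not stated. The shorter list is taken as the false discovery rate of 0.5% and the longer as that of 3%, from how the authors named them. In the unfiltered ChIP and input lists the regions are 270 bp wide and the deposited signal, called the height here, is never below 5. Its scaling to library size is not stated, so scores and heights were used to describe, rank or filter peaks within a list, and no fold was taken between lists. The input list is the one named control by the authors, input being the only control in the labels. Whether it was called on input alone or as input over ChIP is not given in the sources used here. The number of columns from other samples was 0. No list names a strain, so replicates could not be compared and the depth per sample is unknown. The number of peaks is the precision available.

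Start positions were shifted to count from 1. Peaks overlapped when they shared at least 1 bp. Expected overlap came from 1000 random placements of the peaks on their own chromosome, between its first base and the end of its last peak in any list. That span stood for the assembled length, which no source used here gave. It includes bases to which reads cannot be mapped. Peak counts per chromosome were compared with the share of span by two-sided exact binomial tests over 11 chromosomes and scaffolds, with Benjamini-Hochberg adjustment. U and Uextra were left out of these tests, since the filtered lists hold no peak there. Ratios of density have exact 95% intervals. Spacing was compared with 1000 random placements. Scores of 3 pairs of classes were compared by the difference of medians with 100000 permutations, two-sided, and medians have bootstrap intervals from 2000 resamples. Calls were made at an adjusted p of 0.05. The peaks named are the 15 with the highest score on the chromosome arms at the 0.5% rate, a rule set before the data were examined for the case that no annotation fitted. Peaks on the fourth chromosome and the Het scaffolds, the fullest windows and the longest gaps were named after their values were seen.

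The tests were tested on simulated data. Of 20 random placements of 3314 peaks, 2 were called by the overlap test, 0 by the spacing test and 1 by the chromosome test. Peaks were placed independently of each other there, so the effect of clustered peaks on the tests was not covered. Alternatives were the 3% list, the stronger 50% of the 0.5% list, the large arms alone, peaks without an input overlap, other overlap rules, merged neighbours and ranks. Placement 5000 to 20000 bp to either side of each peak was added after seeing the data. So were arms without the 1 Mb next to the centromere. Next to or near the centromere here means the centromere-side end of the arm as listed, without the Het scaffolds. Overlap with positions sharing 200 bp or more with an input peak set aside was also added then. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.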

Results

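L(3)mbt, the product of the lethal (3) malignant brain tumour gene, is a chromatin protein with MBT domains that acts as a tumour suppressor in the larval brain of Drosophila melanogaster. Its binding to the genome was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in larvae of the third instar. The tissue was a mixture of brain and of the imaginal discs of the wing, the haltere and the third leg, from larvae raised at 25 °C. The labels describe 4 libraries. The L(3)mbt ChIP group held 2 samples, from the w1118 and the Canton S strain, which are a white-eyed and a wild-type laboratory stock. The input group held 2 samples of DNA from the same strains without an antibody. The processed data were 4 peak lists. Each stood for a group as a whole, with no value per strain, so no spread between strains and no test across replicates can be given. Intervals and p-values below take the peak as the unit and cover counting error only. The exact tests and intervals also treat peaks as independent. Counts of L(3)mbt peaks per 200 kb window had a variance 1.98 times their mean, so those intervals are likely too narrow and those p-values too small. The sequencing depth behind the lists is unknown.

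The first comparison concerned where the authors listed binding by L(3)mbt, and how those peaks differed in number and height from the peaks listed for input. At the stricter false discovery rate of 0.5%, regions of 400 bp were listed as L(3)mbt peaks, 3264 of them on the 5 large chromosome arms, 33 on the fourth chromosome and 17 on heterochromatic scaffolds. They covered 1.33 Mb. At a rate of 3%, 1258 further regions were listed. The peaks ranged widely in strength. The authors' peak score had a median of 15.6 (95% bootstrap interval 15.2 to 16.2) at the stricter rate. Of those peaks, 25% scored above 35.7, and the highest reached 358.7. The strongest 10% of the peaks held 42.6% of the summed score. All peaks of the stricter list (100%) recurred with identical ends and scores in the longer list. They scored from 7.5025 upwards, and the 1258 further peaks scored from 5.5025 to 7.5. Both rates therefore corresponded to a cutoff on the score.

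The unfiltered ChIP list held 18529 peaks of 270 bp and the unfiltered input list held 46603. Input calls were more numerous and nearly all low. In the ChIP list, 2923 peaks (15.8%, exact 95% interval 15.3 to 16.3%) had a height of at least 20. In the input list, 10 peaks did (0.0215%, exact 95% interval 0.0103 to 0.0395%). A height of at least 100 was reached by 716 ChIP peaks and by 0 input peaks. The median height was 7.12 in the ChIP list and 5.64 in the input list, and no peak of either list lay below 5. The scaling of each list is not stated in the sources used here, so these heights describe each list and do not measure a fold between them. All peaks of the stricter list, called the filtered peaks below, overlapped a peak of the unfiltered ChIP list, and 20.8% of the latter overlapped a filtered peak.

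**Figure D1:**
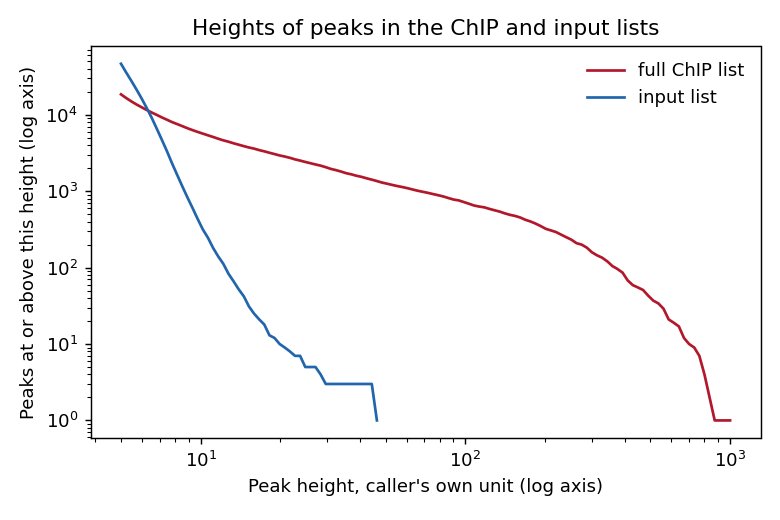
Number of peaks at or above each height (both axes logarithmic, height in the caller's own unit) for the unfiltered ChIP list and the input list. The input curve ends at 46.5, while 716 ChIP peaks have a height of at least 100.

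The 15 highest-scoring L(3)mbt peaks lay on the autosomal arms. 3R carried 6 of them, 2R carried 4, 3L carried 3 and 2L carried 2. Positions are given as in the deposited lists, whose chromosome names are those of genome release 5. The strongest peak was on 3R from 10921417 to 10921816, with a score of 358.7, which was 23.0 times the median. The next were on 3R from 796480 to 796879 with a score of 354.7, on 3R from 12086548 to 12086947 with a score of 333.1 and on 3R from 6500848 to 6501247 with a score of 327.9. On 3L, the region from 14104537 to 14104936 scored 326.3. That from 505988 to 506387 scored 299.2 and that from 19133435 to 19133834 scored 295.0. On 2L, the region from 12520356 to 12520755 scored 325.1 and that from 18859163 to 18859562 scored 306.8. On 2R, the peaks from 21070394 to 21070793, from 4139004 to 4139403, from 2038598 to 2038997 and from 16771979 to 16772378 scored 318.2, 299.6, 285.8 and 280.9. The remaining ones, both on 3R, lay from 21019530 to 21019929 with a score of 301.5 and from 3635897 to 3636296 with a score of 275.5. Among the 15, 0 overlapped an input peak, and 5.70% of all filtered peaks did. The lack of overlap is thus not particular to the 15, and the centres of ChIP and input peaks kept apart in general. The nearest input peak was at least 490 bp away from each of the 15 and had a height between 5.09 and 6.74 in its own list. The matching peaks of the unfiltered ChIP list had heights from 480.1 to 1027.9 in theirs. On X, where none of the 15 lay, the highest peak of the unfiltered ChIP list had a height of 748.5, within that range. A further filtered peak lay within 10 kb of 3 of the 15. The genes at these positions were not analysed here, because no annotation of that release was used.

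The second comparison set the L(3)mbt peaks against the input list. The sources used here do not state whether that list was called on input alone or as input over ChIP, so its peaks may be places of excess over ChIP instead of plain background. The centres of the lists kept apart. No filtered peak had an input peak centred within 100 bp, where random placement gave 236.3, and in the unfiltered ChIP list 1 of 18443 peaks did, where random placement gave 1317. Counts of overlaps are therefore partly set by how the lists were made. Of the filtered peaks, 189 (5.70%) overlapped an input peak by at least 1 bp. After 1000 random placements on the same chromosomes, 21.2% did (95% of placements 19.8 to 22.6%). The ratio was 0.27 (two-sided permutation test of peak positions, p = 0.0020, the smallest that 1000 placements can give). With positions sharing 200 bp or more with an input peak set aside, 187 of 3312 peaks (5.65%) overlapped an input peak. Random placement gave 12.9%, a ratio of 0.44 (permutation test, p = 0.0020, the smallest possible). That limit was set after the data were seen. Input density rose gradually, from 73.9 per Mb at 100 to 200 bp to 247.4 at 400 to 500 bp. The exclusion may thus reach past the limit, and the ratio of 0.44 cannot be told apart from how the lists were made. Arm by arm, the ratio over all positions ranged from 0.24 on 3L to 0.29 on 2R and was 0.26 on X. On the fourth chromosome, 4 of 33 peaks overlapped an input peak against 26.1% at random, a difference that did not pass the permutation test (p = 0.078). Peaks with an overlapping input peak were weaker. Their median score was 12.2 (n = 189) against 16.0 (n = 3125) for the others, a difference of -3.76 (permutation test, 100000 resamples, two-sided, p = 0.0052, adjusted over 3 contrasts 0.0078). Among the stronger 50% of the peaks the difference was -11.7 and did not pass the permutation test (adjusted p = 0.12). Whether input was subtracted from the scores is not stated. If it was, or if input was called over ChIP, lower scores beside input peaks could follow by construction. 

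**Figure D2:**
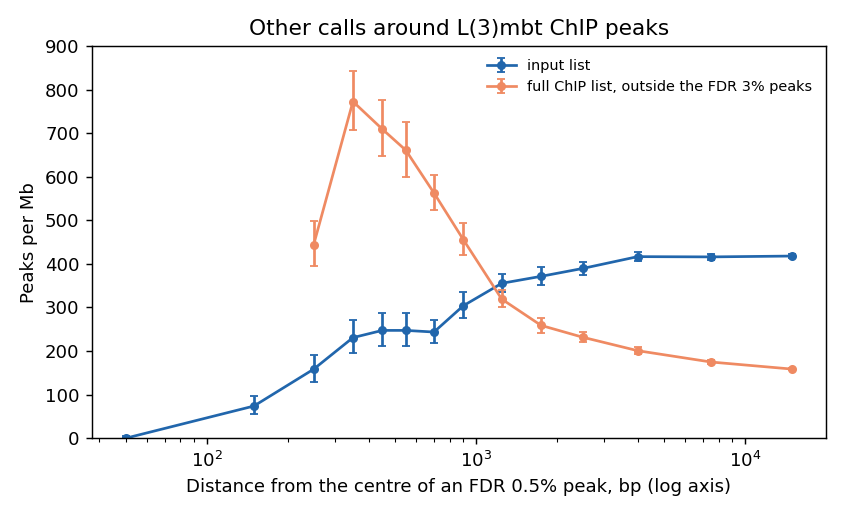
Peaks per Mb (vertical axis) at increasing distance in bp between centres from the filtered L(3)mbt peaks (logarithmic axis). Shown are the input list and those peaks of the unfiltered ChIP list centred 200 bp or more from the centre of any peak at the 3% rate. The nearest of the latter still overlap a listed peak. Bars are exact 95% Poisson intervals. Input peaks rise from 0 at the centre to 418.0 per Mb at 10000 to 20000 bp. The other ChIP calls are at 443.6 per Mb at 200 to 300 bp and 772.5 at 300 to 400 bp, and then fall to 158.7 at 10000 to 20000 bp.

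The third comparison asked how L(3)mbt peaks were distributed over the chromosomes. The euchromatic arms carried nearly all of them. The 5 large arms held 3264 peaks, or 27.4 per Mb (exact Poisson 95% interval 26.5 to 28.4). The 5 Het scaffolds, which hold mapped pericentric heterochromatin, carried 17 peaks, or 1.98 per Mb (1.16 to 3.17). The density on the Het scaffolds was 0.072 times that on the arms (95% interval 0.042 to 0.116). The input list was also sparse there, with 0.164 times the density on the arms (0.150 to 0.178). Of the Het scaffolds, 2RHet, 3LHet and 3RHet each had 5 peaks, where the span up to the last listed peak gave 84.0, 65.4 and 64.7 (exact binomial tests, adjusted over 11 chromosomes, 1.2e-28, 2.3e-21 and 3.2e-21). The single peaks on 2LHet and on XHet did not pass the exact binomial test against the 4.36 and 2.19 that this span gave (adjusted p = 0.23 and 0.93). The span was 0.169 Mb on 2LHet and 0.085 Mb on XHet. A scaffold that goes on beyond its last listed peak would have a higher expected count, so these tests may miss a shortage. A few Het peaks were strong. The region on 3RHet from 2107012 to 2107411 scored 188.9, above 98.2% of the list.

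The fourth chromosome is small and largely heterochromatic, yet gene-bearing. It carried 33 L(3)mbt peaks, or 25.9 per Mb (17.8 to 36.3). That was 0.94 times the density on the large arms, with a 95% interval from 0.65 to 1.33, so a difference within that range was not detectable with so few peaks. In the larger unfiltered ChIP list the ratio was 0.79 (0.67 to 0.93, exact binomial test, adjusted over 12 ratios p = 0.0060), and in the input list it was 1.32 (1.22 to 1.42, adjusted p = 6.5e-11). Calls of the unfiltered ChIP list gathered around filtered peaks, so its test overstates its precision. The large arms include X, where input peaks were sparse (149.7 per Mb), which raises the input ratio. Input peaks were at 501.4 per Mb on the fourth chromosome, 380.7 on the large arms and 434.3 on the 4 autosomal arms alone. The strongest L(3)mbt peaks of the fourth chromosome lay from 89194 to 89593, with a score of 184.1, from 1000451 to 1000850, with a score of 172.6, and from 1133483 to 1133882, with a score of 143.8.

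The X chromosome carried 609 L(3)mbt peaks, or 27.2 per Mb, against 27.5 per Mb on the 4 autosomal arms. The ratio was 0.99 (95% interval 0.90 to 1.08). The median score on X was 15.5 against 15.7 on the autosomal arms, a difference of -0.28 that did not pass the permutation test (adjusted p = 0.71). The input list behaved otherwise. It held 149.7 peaks per Mb on X and 434.3 on the autosomal arms, a ratio of 0.345 (0.333 to 0.357).

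Among the large arms, 2R held 636 peaks, or 1.17 times the number by length (exact binomial test, adjusted p = 6.6e-05), and 3R held 796, or 1.11 times (adjusted p = 0.0024). With the Het scaffolds and the fourth chromosome left out, the ratios by the same exact test were 1.10 for 2R (adjusted p = 0.059) and 1.04 for 3R (adjusted p = 0.26), so neither arm was called. Shares on 2L, 3L and the fourth chromosome did not pass the test under any setting, and that on X passed in 1 of them.

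**Figure D3:**
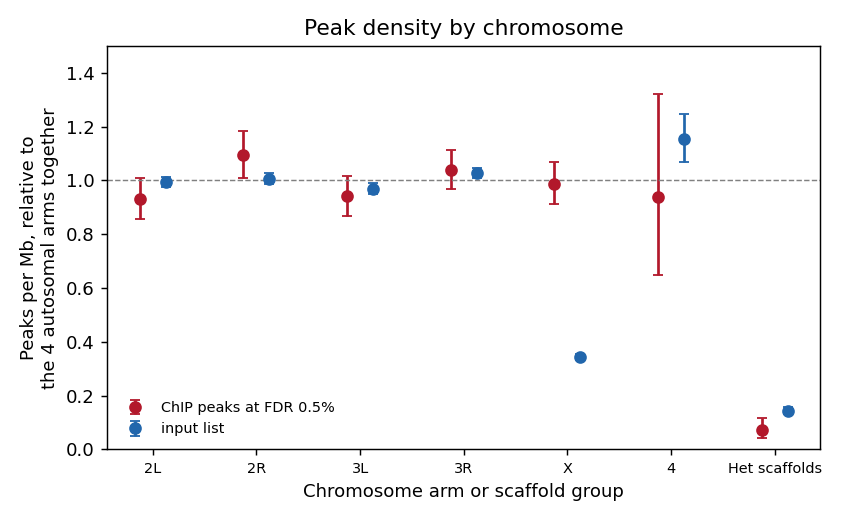
Peaks per Mb relative to the 4 autosomal arms together (vertical axis), by chromosome arm or scaffold group, for filtered L(3)mbt peaks and for the input list. Bars are exact 95% Poisson intervals of each density. On X the L(3)mbt ratio is 0.99 and the input ratio 0.345, and both lists are sparse on the Het scaffolds.

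The fourth comparison asked whether L(3)mbt peaks lay in clusters. The median distance from one peak to the next was 18252 bp, against 25308 bp after random placement (95% of placements 24475 to 26205 bp, ratio 0.72, permutation test p = 0.0020, the smallest possible). Neighbours less than 1000 bp apart numbered 186, where random placement gave 89.5. Those less than 5000 bp apart numbered 683, where random placement gave 423.0. Counts per 200 kb window had a variance 1.98 times their mean, against 1.02 at random. Of 592 such windows, 31 held no peak, where random placement gave 2.45. Some empty windows lay near a centromere and held few input peaks, such as 2 on X from 21600001 and 14 on 2R from 200001. Others did not, such as 2R from 6200001 with 106. Random placement covered all these stretches, and the spacing of input peaks was not compared. How far uneven coverage adds to the gathering was therefore not tested. The fullest window was on 2L from 19400001 to 19600000, with 17 peaks against a mean of 5.50, although random placement reached a maximum of 14.0 on average and the excess did not pass the permutation test (p = 0.064). Windows with 14 peaks lay on 2L from 2800001 to 3000000, on 2R from 13400001 to 13600000, on X from 7800001 to 8000000 and on X from 17600001 to 17800000.

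The longest stretch without an L(3)mbt peak on a large arm was on 2R from 712109 to 1492203, near the centromere, and held 168 input peaks. The next was on 3L from 23088870 to 23707853, also near the centromere, with 78 input peaks. A stretch away from the centromere on 2R from 15615089 to 16151212, 536 kb long, held 270 input peaks and 37 peaks of the unfiltered ChIP list. Peaks with another filtered peak within 2000 bp scored lower than the rest. Their median score was 13.2 (n = 626) against 16.4 (n = 2688), a difference of -3.16 (permutation test, adjusted p = 0.00015). Among the stronger 50% of the list, the difference was -3.30 and did not pass the permutation test (adjusted p = 0.44).

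**Figure D4:**
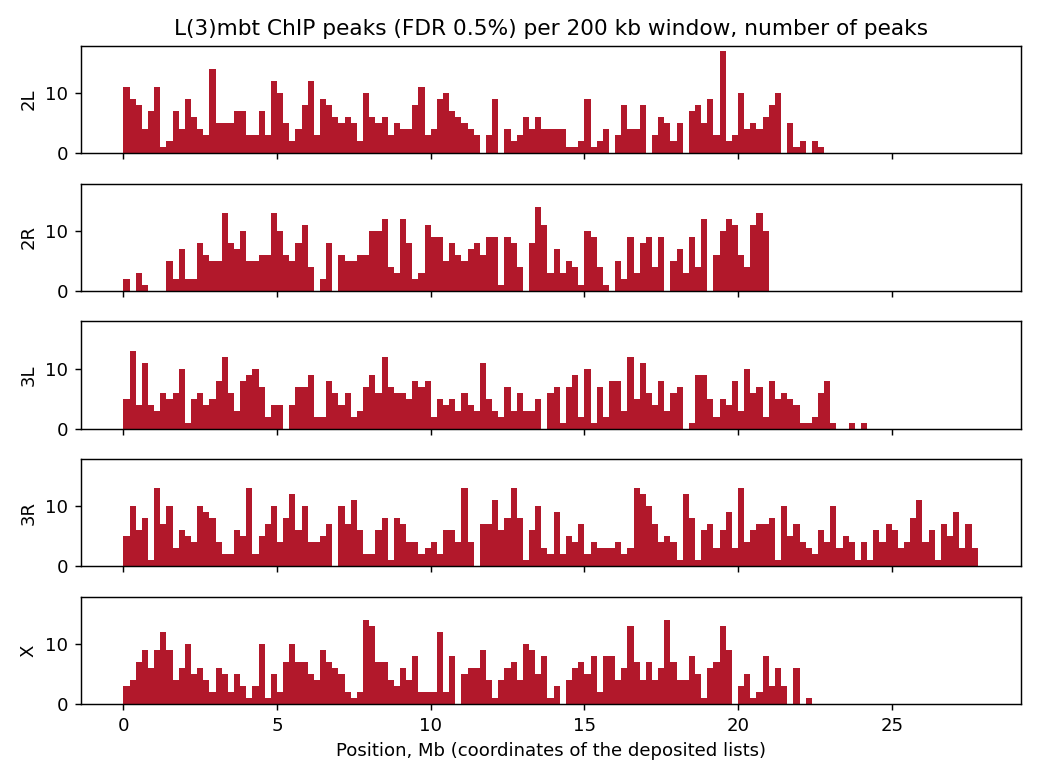
Number of filtered L(3)mbt peaks (vertical axis) per 200 kb window along the 5 large chromosome arms (position in Mb, coordinates of the deposited lists). The fullest window, on 2L from 19400001, holds 17 peaks, and 31 of 592 windows hold none.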

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

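All tests of explanations in this part were chosen after the results were seen.

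On the unplaced scaffold set Uextra, which the filtered lists do not include, the unfiltered ChIP list held 75 peaks with a highest height of 253.2, and 8 of them reached 50. The input list held 33 peaks there with a highest height of 23.8.

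The X chromosome carried 0.345 times the autosomal density of input peaks, while L(3)mbt peaks were at 0.99 times (95% interval 0.90 to 1.08). Lower listed signal on X in the input list is a possible explanation that the heights leave open. If autosomal input heights are multiplied by 0.832, the number above the minimum height of 5 matches that on X, and the median height of the rest becomes 5.541 (95% interval 5.533 to 5.558). The median observed on X, 5.53, lies just below that interval, and its own interval (5.50 to 5.56) overlaps it. For fewer X copies per cell, acting alike on both kinds of library, the same factor predicts weak ChIP peaks on X at 0.538 times the autosomal density if the lists were scored independently. They were at 1.02 times (0.960 to 1.07), which goes against fewer copies acting alone in that case. Scoring of both lists against each other would cancel copy number in both and leave no shortfall. Acting alone, fewer copies thus stay open only if ChIP heights are relative to input and input heights are not, which the sources do not state. The weak ChIP calls may include L(3)mbt binding, so a broad signal on X could also offset fewer copies under independent scoring. A different share of male larvae in the ChIP and input material, a difference in how the lists were scaled and a broad L(3)mbt signal on X stay open and untested.

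Input peaks were scarce around L(3)mbt peaks. At the centre, the scarcity fits lists made exclusive of each other, since 1 unfiltered ChIP peak had an input peak within 100 bp where random placement gave 1317. At 200 to 1000 bp the density was still 0.592 times that at 10000 to 20000 bp (0.556 to 0.628). The same exclusion may thin input peaks there, since other unfiltered ChIP calls were 3.64 times as dense as at 10000 to 20000 bp. Spill-over of ChIP signal into the flanks may contribute. The density around the strongest 25% of peaks was 0.863 times that around the weakest 25%, with an interval from 0.732 to 1.02 that includes 1, which keeps it open. An input signal that is truly lower at bound regions was not tested.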

How the results depend on the processing

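Of 84 repeats over 19 results, 67 kept their direction, call or size. The overlap of L(3)mbt peaks with input peaks stayed below random placement in 6 alternatives. The ratio ran from 0.18 times (stronger 50% of the list) to 0.44 times (positions sharing 200 bp or more with an input peak set aside). The exclusion of the lists may reach past that limit and lower each of these ratios. A further alternative, with at least 200 bp of the peak covered (0.0063 times), only restates that the lists exclude each other. Spacing stayed below random in its 5 alternatives, from 0.66 to 0.88 times, none of which left out the stretches near the centromeres. The 3% list moved the median score to 11.2. The stronger 50% of the list, by construction, held 1657 peaks with a median score of 35.7. On these fewer peaks, 2R was at 1.07 times its length share and no longer called, while 3R was at 1.21 times and stayed called (exact test, adjusted p = 4.1e-05). The score differences for peaks with an input overlap (-11.7) and with a neighbour (-3.30) were no longer called there. On the large arms alone, 2R (1.10) and 3R (1.04) were no longer called, since the sparse Het scaffolds had left the expected share. Without peaks that overlap an input peak, X rose to 1.09 times and passed the exact test (adjusted p = 0.031), which follows from the lower number of input peaks on X. Chromosomes not called in the list as reported crossed 1, namely 2L (1.00 in the stronger 50%, 1.01 without the 1 Mb next to the centromere), 3L (0.998 in the stronger 50%, 0.943 on the large arms alone), X (0.990 on the large arms alone) and the fourth chromosome (0.927 in the 3% list, 0.937 without input overlaps, 0.982 without the centromeric Mb). No paired analysis was possible because the lists carry no value per strain, and for that reason no sample could be left out in turn. The unknown depth limits any statement on weak or missing peaks. Alternatives that need a genome or annotation were not run.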

Other observations

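The comparisons and tests in this part were chosen after the data were seen. L(3)mbt peaks were sparse at the centromere-side ends of 4 of the 5 large arms, 3R being the exception. These ends do not include the Het scaffolds, which are listed separately. The exception holds for the end of the 3R arm alone, since 3RHet held 5 peaks where its span gave 64.7. In the 1 Mb at the centromere-side end of each of the 5 large arms, 54 peaks were listed in all. That was 0.38 times the density of the remaining arms (95% interval 0.29 to 0.50). The 3L arm had 2 peaks there, 2L had 5, 2R had 6 and X had 11, while 3R had 30, close to the 28.5 per Mb of its remainder. Input peaks were also fewer there, at 0.56 times (0.53 to 0.59), and 3R was the exception for them too. It had 544 input peaks in this stretch, against 442.7 per Mb in its remainder. Input peaks there numbered 208 on 2L, 142 on 2R, 116 on 3L and 76 on X. The remainders of those arms held 441.6, 451.5, 434.2 and 153.2 per Mb. The pattern over the arms is thus not particular to L(3)mbt peaks. How the input list was called is not stated, so the comparisons with it that follow describe the lists. On the 4 autosomal arms the odds of lying in this stretch were 0.67 times as high for L(3)mbt peaks as for input peaks (Fisher's exact test, 95% interval 0.48 to 0.91, adjusted over 5 regions p = 0.014). On the Het scaffolds, relative to the autosomal arms, they were 0.50 times as high (exact test, 0.29 to 0.81, adjusted p = 0.0086). On the fourth chromosome the odds ratio was 0.81 (exact test, 0.55 to 1.16, adjusted p = 0.29) and in the 1 Mb at the distal ends it was 1.15 (0.96 to 1.37, adjusted p = 0.15), neither of which passed.

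Peaks of the unfiltered ChIP list that lay 200 bp or more from any peak at the 3% rate gathered around the filtered L(3)mbt peaks. At 200 to 1000 bp they were 3.64 times as dense (3.48 to 3.82) as at 10000 to 20000 bp, and 2902 of 13697 lay within 1000 bp of a filtered peak. A regional rise in calls stays open. Input peaks at the same distances were at 0.592 times their distant density, but the lists exclude each other, which may by itself thin input peaks where ChIP calls gather. Shoulders of the filtered peaks, split off by the caller, may account for part of it and would give more such calls around stronger peaks. The net number around the strongest 25% of filtered peaks was instead 0.863 times that around the weakest 25%, though the interval (0.739 to 1.01) includes 1. The calls were higher close by, with a median height of 7.03 at 200 to 600 bp, 6.53 at 600 to 1000 bp and 6.17 at 5000 bp or more, and 33, 2 and 0 of them reached 50, although an isolated call of that height would itself tend to be listed at the 3% rate and so be left out here. Shoulders therefore stay open. L(3)mbt binding that extends beyond the called 400 bp was not tested.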
